A study of Mus musculus with 6 samples.

How the data were processed

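RNA was measured by mRNA sequencing in 6 liver samples of C57 mice. In 3 samples the animals had received Ad-Dyrk1b, an adenovirus that carries mouse Dyrk1b, and in 3 they had received Ad-EGFP, a control adenovirus. Per the labels' protocols, enriched mRNA was fragmented, made into libraries with a NEBNext Ultra kit and sequenced on an Illumina NovaSeq. The labels state no strand setting for the counting. The aligner, the counting tool and the annotation release are not given in the sources used here. Per the submitters' processing notes, the genome build was mm10 and DESeq2 was used, with no version named. The labels do not say that the samples of a group came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

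The deposited table held whole-number counts per gene and library, per the file headers, with no normalization. It also held FPKM values made by the authors (counts scaled to gene length and library size), per the file headers. The authors' group means of FPKM, the log2 ratio of those means, a p-value and its adjusted value completed the deposited table. The deposited log2 ratio equalled the log2 ratio of the mean columns within 1e-09 in all 22274 genes. Each group was taken from the treatment label, and each column was assigned by its name.

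Of the 22274 genes, 5089 had no count in any library. Identifiers of 22219 genes were found in GENCODE mouse release M21, which uses the same genome build and gave the coordinates. There were 21 symbols that occurred more than once and 12 genes had no symbol, so genes were handled by identifier. The filter of edgeR (filterByExpr, minimum count 10, minimum total count 15) left 13201 genes for testing.

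The 2 groups of 3 were compared with edgeR 4.0.16 (R 4.3.3), using TMM normalization, a robust quasi-likelihood fit and a two-sided quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg over all tested genes, and genes with an adjusted p under 0.05 were called. Log2 fold changes are Ad-Dyrk1b over Ad-EGFP, and the value after ± is the standard error. FPKM values are the mean ± SD over 3 libraries of a group. The fit was tested on simulated counts for this comparison, with 13201 genes of which 200 were changed. It called 71% of the 2-fold changes and 97% of the 4-fold changes, and 10.2% of its calls were false.

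Before the data were examined, 45 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with 5 or more tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2. Camera used a preset inter-gene correlation of 0.01, and p-values were adjusted over the 43 lists tested. In simulated data camera called 10 of 10 shifted lists and 0 of 30 unchanged lists. Simulated genes varied independently of each other, so this does not test false calls in lists whose members vary together. The interferon list, for example, had an estimated correlation of 0.455. Each list was tested again with an estimated inter-gene correlation and with fry. Fry's directional p asks whether the members move one way on balance, and its mixed p asks whether they change in either direction. Neither compares a list with other genes. Lists share some members. For example, Cyp1a2, Cyp2a5 and Cyp2e1 stand in both the pericentral and the xenobiotic lists. Annotation terms given in the deposited table (pathways and gene ontology terms, 10 to 500 tested genes each) were tested by one-sided Fisher's exact test against all tested genes.

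The rule for named genes took Dyrk1b and 11 genes fixed by name, of which 1 is not reported here. It also took the 12 higher and the 12 lower called genes with the largest absolute log2 fold change. Those genes needed a mean of 1 FPKM or more, groups that did not overlap and a symbol that is neither a clone name nor a pseudogene. Dyrk1b is itself among the 12 higher genes. From each list the rule allowed up to 4 members with the smallest p. Of these, members whose calls held when any 1 library was left out were preferred as examples. Gsn, Asl, Cyp2b10, Igfbp2, Orm2, Sdf2l1, Per1 and Bhlhe40 lie outside the rule and were chosen after their values were seen.

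Total counts per library ranged from 17326516 to 20024888, so 3 counts correspond to 0.150 to 0.173 CPM. Such floors cover counting error only, since PCR copies are not independent molecules. Members of the Mup, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Sult, Saa and Orm families are near-identical copies, so their individual values are uncertain and family sums are given where they matter. Of 111 named genes, 20 overlap another protein-coding gene, and without a stated strand setting their counts are uncertain. These are Igf2, Lrp2bp, Lgals2, Ccnd1, Srebf1, Oat, Glul, Sult1a1, Acot3, Elovl3, Cyp51, Abcg5, Apoc2, Acss2, Acaca, Mlst8, Irf7, Mcm7, Prodh and Gls2. Counts of Dyrk1b do not separate transcripts of the virus from those of the mouse gene.

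The alternatives were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test and limma-voom. Others were no low-count filter, a stricter filter (mean of 1 FPKM or more) and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1). The FPKM fits used genes at 0.5 FPKM or more in 3 or more libraries. The replicate number as a block and the omission of each library in turn completed the set. Lists of pancreatic acinar and adipocyte markers had too few tested members, with highest counts of 9 and 61 in any library, and were left out.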

Results

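Livers of C57 mice given an adenovirus that carries mouse Dyrk1b (Ad-Dyrk1b) were compared with livers given a control adenovirus (Ad-EGFP), with 3 samples in each group. Dyrk1b encodes a dual-specificity tyrosine-regulated kinase, and the series concerns its role in the liver in the control of systemic glucose. Total counts per library ranged from 17326516 to 20024888. Log2 expression correlated at r = 0.982 to 0.986 between libraries of a group and at r = 0.960 to 0.970 between groups, across genes, which are not independent replicates. The first principal component held 52.4% of the variance and separated the groups. The second held 14.3% and set Ad-Dyrk1b replicate 3 apart, at -26.7.

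Dyrk1b itself (ENSMUSG00000002409, chromosome 7, 28179469 to 28187294, plus strand, mm10) stood at 86.5 ± 21.1 FPKM in Ad-Dyrk1b and 4.31 ± 0.595 FPKM in Ad-EGFP livers (SD, n = 3 each). All 3 Ad-Dyrk1b libraries (62.2, 101 and 96.5 FPKM) lay above all 3 Ad-EGFP libraries (3.81, 4.97 and 4.16 FPKM). Its log2 fold change was 4.49 ± 0.24, or 22.4-fold (edgeR adjusted p = 1.33e-05).

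**Figure D1:**
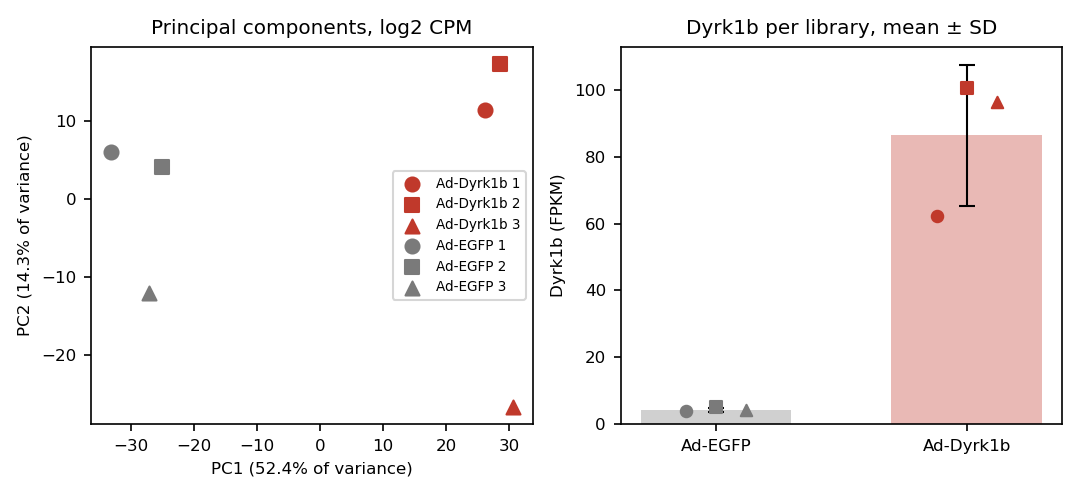
Left, each library on the first principal component (52.4% of variance) and the second (14.3%) of log2 expression, coloured by group; right, Dyrk1b in FPKM, with a bar for the mean, a line for the SD and a point for each of 3 libraries per group. The groups separate on the first component, and Dyrk1b averages 86.5 FPKM in Ad-Dyrk1b against 4.31 FPKM in Ad-EGFP livers.

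Of 13201 genes tested, 972 were higher and 635 lower in Ad-Dyrk1b livers (edgeR adjusted p under 0.05), which is 12.2% of the genes. Of these calls, 430 changed by 1 log2 unit or more, 324 of them higher and 106 lower. Of the 13201 tested genes, the groups did not overlap in 4334, or 32.8%, where chance gives 10% with 3 against 3. The share of higher calls was 60.5% here and 42.3% with limma-trend on log2(FPKM + 1), where 546 genes were higher and 744 lower. The counts also fell when 1 library was left out. Without Ad-Dyrk1b replicate 2, Ad-EGFP replicate 1 or Ad-EGFP replicate 3, 612, 615 and 641 genes were higher. Without Ad-Dyrk1b replicates 1, 2 or 3, or Ad-EGFP replicates 1 or 3, 381, 326, 396, 294 and 414 genes were lower.

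Several of the genes with the largest rises encode sulfotransferases, cytochromes P450 and major urinary proteins. Fabp6, the ileal bile acid-binding protein (chromosome 11, 43596049 to 43601540), had 35, 20 and 35 counts in the Ad-Dyrk1b libraries and 0 in each Ad-EGFP library. Taking 3 counts over the control group as the floor, it was at least 29.6-fold higher. The sulfotransferase genes Sult3a1, Sult3a2 and Sult2a7 rose by 5.89 ± 0.66, 4.94 ± 0.47 and 4.23 ± 0.36. Without Ad-Dyrk1b replicate 3, whose 21.6 FPKM exceeded the 7.59 and 7.04 FPKM of the other Ad-Dyrk1b libraries, the value for Sult3a1 was 5.20. The cytochrome P450 genes Cyp3a41b and Cyp3a16 rose by 5.89 ± 0.50 and 5.74 ± 0.70. Without Ad-EGFP replicate 1 these values were 6.52 and 7.11. The call for Cyp3a16 was lost without Ad-Dyrk1b replicate 2 (edgeR adjusted p = 0.0519) or Ad-EGFP replicate 2 (edgeR adjusted p = 0.0546), in a range of 5.89e-06 to 0.0546. The major urinary protein genes Mup17, Mup15 and Mup19 rose by 5.59 ± 0.56, 5.36 ± 0.53 and 5.21 ± 0.47. Without Ad-EGFP replicate 2 the value for Mup15 was 5.97. Dct, an enzyme of melanin synthesis, rose by 4.41 ± 0.56 and the anion exchanger gene Slc4a9 by 4.32 ± 0.36. Sult3a1, Sult3a2 and Dct had 1 to 6 counts in each Ad-EGFP library, so their values rest on few counts. How reads that match several copies of the Sult, Cyp3a and Mup families were counted is not given in the sources used here, so the values of single copies are uncertain. Gsn, which encodes the actin-severing protein gelsolin and was named after its values were seen, had the smallest p of all genes. It stood at 127 ± 5.82 FPKM against 9.84 ± 2.03 FPKM (SD, n = 3 each), a log2 fold change of 3.78 ± 0.15 (edgeR adjusted p = 5.47e-08).

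The largest fall was in Rec8, a cohesin subunit of meiosis (chromosome 14, 55618037 to 55625395). It stood at 0.413 ± 0.0950 FPKM in Ad-Dyrk1b and 16.6 ± 3.74 FPKM in Ad-EGFP livers (SD, n = 3 each), a log2 fold change of -5.25 ± 0.24 (edgeR adjusted p = 1.44e-07). The growth factor gene Igf2 fell by 3.63 ± 0.33 and the protocadherin gene Pcdh20 fell by 3.45 ± 0.35. The adenylate kinase gene Ak1 fell by 2.98 ± 0.22. Saa3, a serum amyloid A gene, fell by 2.75 ± 0.39, a call lost without Ad-Dyrk1b replicate 2 (edgeR adjusted p = 0.0641, range 0.000263 to 0.0641). Fndc10, Lrp2bp and Psrc1 fell, with log2 fold changes of -2.32 ± 0.21, -2.14 ± 0.27 and -2.12 ± 0.21. Cpt1c, a carnitine palmitoyltransferase isoform best known from brain, fell by 1.96 ± 0.27, and the histone gene H3c8 fell by 1.87 ± 0.34. The galectin gene Lgals2 fell by 1.92 ± 0.44 and the retinol-binding protein gene Rbp2 fell by 1.91 ± 0.48. Without Ad-Dyrk1b replicate 3 the log2 fold change of Lgals2 was -2.66, and without Ad-Dyrk1b replicate 2 that of Rbp2 was -2.53. The call for Lgals2 was lost without Ad-Dyrk1b replicate 1 or 2 (edgeR adjusted p = 0.0608 and 0.0596, range 0.00319 to 0.0608). The call for Rbp2 was lost without any library but Ad-Dyrk1b replicate 2 (edgeR adjusted p = 0.0181 to 0.0681).

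**Figure D2:**
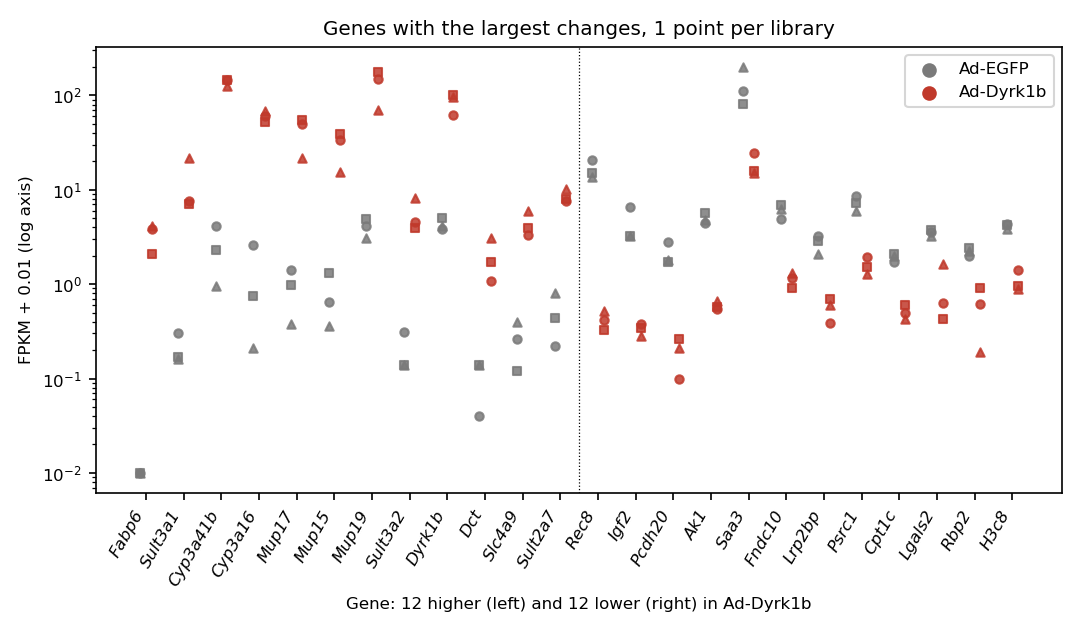
FPKM plus 0.01 on a log axis for the 12 genes with the largest rises and the 12 with the largest falls, with a point for each of 3 libraries per group and marker shapes for replicate numbers. The groups do not overlap for any of these 24 genes; Fabp6 lies at 0 in every Ad-EGFP library.

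Genes of the pericentral zone, the hepatocytes around the central vein, were higher in Ad-Dyrk1b livers, and 10 of 13 rose (12 adjusted over the list alone). Oat (ornithine aminotransferase) rose by 1.39 ± 0.16, Slc1a2 (a glutamate transporter) by 1.13 ± 0.15, Cyp2e1 by 1.04 ± 0.16 and Glul (glutamine synthetase) by 0.73 ± 0.11. The median was 0.99 (camera adjusted p = 7.27e-08, and camera adjusted p = 0.143 with an estimated correlation). Of 13 periportal genes, 3 rose and 1 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.677). Pigr, the polymeric immunoglobulin receptor, rose by 1.72 ± 0.17, Cdh1 (E-cadherin) by 0.93 ± 0.12 and Hal (histidine ammonia-lyase) by 0.79 ± 0.15. The periportal gene that fell was Gls2, by 0.53 ± 0.14. Its call was lost without Ad-Dyrk1b replicate 1 or 3 or Ad-EGFP replicate 1 or 3 (edgeR adjusted p = 0.0120 to 0.120 with 1 library left out).

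Xenobiotic metabolism genes had 5 of 19 members higher (7 adjusted over the list alone) and a median of 0.14. The sulfotransferase gene Sult1a1 rose by 1.09 ± 0.12, Cyp2c50 by 0.89 ± 0.16 and Cyp2a5 by 0.81 ± 0.14, and Cyp2e1 is the fourth. The fifth, Cyp2b10, rose by 1.18 ± 0.21 and was named after its values were seen. The list passed (camera adjusted p = 0.0193, and camera adjusted p = 0.716 with an estimated correlation). It did not pass without Ad-Dyrk1b replicate 2 (camera adjusted p = 0.126) or Ad-EGFP replicate 3 (camera adjusted p = 0.0721; range 0.00286 to 0.126 with 1 library left out).

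Both lists of sex-biased liver genes were higher. Of 12 female-biased genes 8 rose (9 adjusted over the list alone), with a median of 1.49 (camera adjusted p = 1.94e-06, and camera adjusted p = 0.716 with an estimated correlation). The hydroxyacid oxidase gene Hao2 rose by 3.19 ± 0.23, Cyp2b13 by 3.18 ± 0.14 and Sult2a1 by 1.18 ± 0.15. The thioesterase gene Acot3 stood at 66.1 ± 3.69 FPKM in Ad-Dyrk1b and 23.6 ± 5.29 FPKM in Ad-EGFP livers (SD, n = 3 each). Of 10 male-biased genes 4 rose (5 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 0.0120, and camera adjusted p = 0.716 with an estimated correlation). The fatty acid elongase gene Elovl3 rose by 1.60 ± 0.21, Cyp4a12b by 1.53 ± 0.23 and Mup20 by 1.07 ± 0.16.

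**Figure D3:**
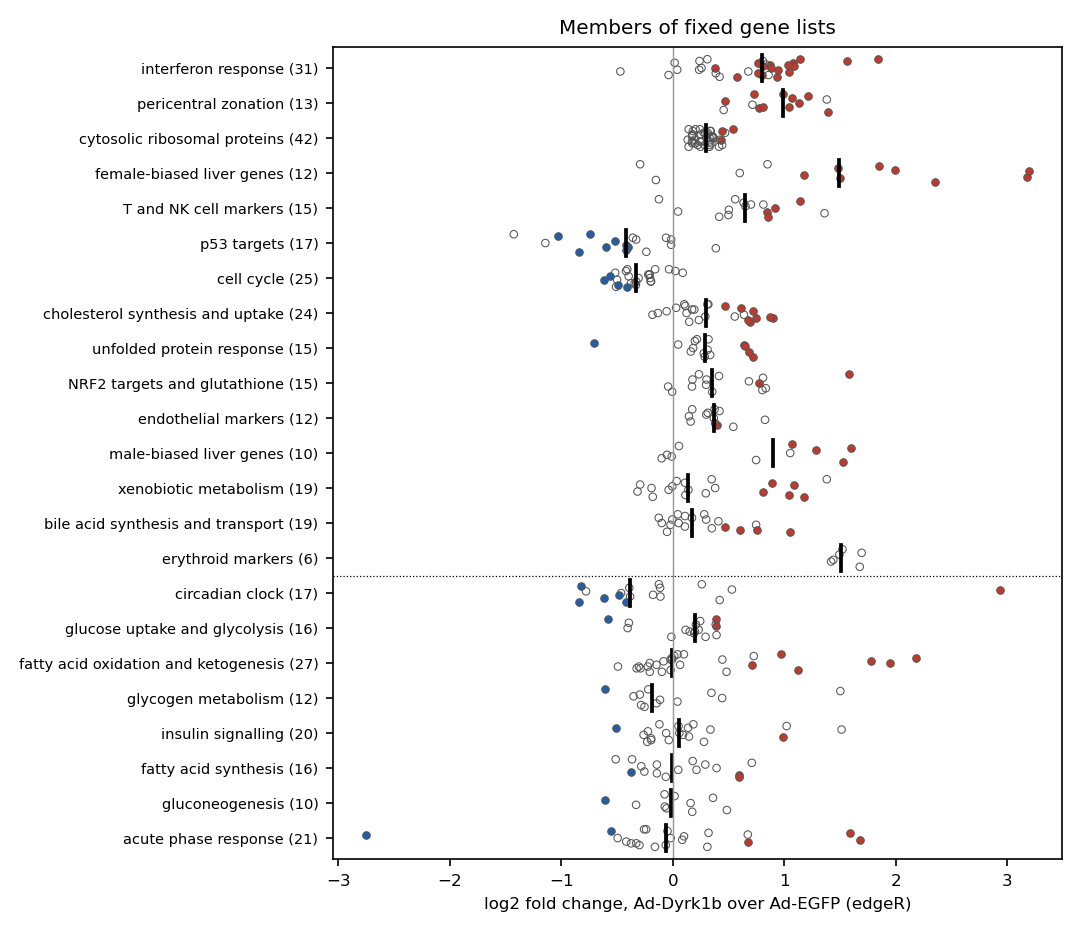
Log2 fold change of each tested member of 23 gene lists, with filled points for called genes (red higher, blue lower), open points for genes not called and a bar for the median; the number of tested members is in parentheses. The 15 lists above the dotted line passed with camera at the preset correlation, 13 higher and 2 lower, and 8 of the other lists stand below it.

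Among lipid genes, 8 of 24 cholesterol synthesis and uptake genes rose (8 adjusted over the list alone), with a median of 0.30. The sterol carrier gene Stard4 rose by 0.87 ± 0.14, and the sterol synthesis genes Cyp51, Hsd17b7 and Dhcr7 by 0.72 ± 0.13, 0.70 ± 0.14 and 0.67 ± 0.12. The list passed (camera adjusted p = 0.00124, and camera adjusted p = 0.716 with an estimated correlation). The groups overlapped in its mean log2 level, centred over the 6 libraries, with -0.0271 in Ad-Dyrk1b replicate 2 and -0.00207 in Ad-EGFP replicate 1. The level was lowest in Ad-EGFP replicate 2, at -0.406. Of 19 bile acid genes 4 rose (7 adjusted over the list alone), with a median of 0.17. The nuclear receptor gene Nr0b2, a repressor of bile acid synthesis, rose by 0.76 ± 0.13, the bile acid ligase gene Slc27a5 by 0.60 ± 0.13 and the sterol exporter gene Abcg5 by 0.47 ± 0.10. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of 0.05 ± 0.29 (edgeR adjusted p = 0.936), and its sign differed between settings. The bile acid list passed (camera adjusted p = 0.0304, and camera adjusted p = 0.716 with an estimated correlation). It did not pass without Ad-Dyrk1b replicate 2 or 3 or Ad-EGFP replicate 3 (camera adjusted p = 0.110, 0.0754 and 0.0923; lowest 0.00158 with 1 library left out). Its median was 0.11 without Ad-Dyrk1b replicate 3, 0.26 without Ad-Dyrk1b replicate 1 and 0.27 without Ad-EGFP replicate 2.

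Fatty acid oxidation genes did not pass as a list (camera adjusted p = 0.269), with a median of -0.00663 and 13 of 27 members above 0. Of the 27, 6 were called higher (8 higher and 2 lower adjusted over the list alone). The fatty acid hydroxylase genes Cyp4a10 and Cyp4a14 rose by 2.18 ± 0.15 and 1.12 ± 0.13, and the pantetheinase gene Vnn1 by 1.78 ± 0.17. Of 16 fatty acid synthesis genes, 2 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.676). Elovl5 (an elongase) rose by 0.60 ± 0.13 and Acss2 (acetyl-CoA synthetase) by 0.59 ± 0.13. Acaca (acetyl-CoA carboxylase) fell by 0.37 ± 0.10, a call kept only without Ad-EGFP replicate 3 among the fits that left out 1 library (edgeR adjusted p = 0.0334 to 0.123). Fasn (fatty acid synthase), Scd1 (stearoyl-CoA desaturase) and Srebf1 (a regulator of lipid synthesis) were not called, with -0.06 ± 0.26, 0.21 ± 0.28 and -0.51 ± 0.29 (edgeR adjusted p = 0.902, 0.661 and 0.298). With the replicate number as a block Srebf1 was called lower (edgeR adjusted p = 0.00656). Of 15 apolipoprotein and lipoprotein remodelling genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0892). Apom rose by 0.87 ± 0.12 and the lipase gene Lipc by 0.68 ± 0.14, and Apoc2 fell by 0.79 ± 0.15. Of 17 triglyceride synthesis and lipid droplet genes edgeR called 0, adjusted over all genes or over the list alone (camera adjusted p = 0.379). At an unadjusted p under 0.05, 2 were higher and 2 lower. DESeq2 called 1 higher and 2 lower, and limma-voom called 0.

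Of 10 gluconeogenesis genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.867). Pck1 and G6pc, the key enzymes of gluconeogenesis, had log2 fold changes of -0.07 ± 0.21 and -0.07 ± 0.21 (edgeR adjusted p = 0.850 and 0.857). Pck1 stood at 640 ± 199 FPKM in Ad-Dyrk1b and 722 ± 31.6 FPKM in Ad-EGFP livers (SD, n = 3 each). Fbp1 (fructose bisphosphatase) fell by 0.61 ± 0.14 (edgeR adjusted p = 0.0153). Its call was lost without Ad-Dyrk1b replicate 1, Ad-EGFP replicate 1 or Ad-EGFP replicate 3 (edgeR adjusted p = 0.0515, 0.0659 and 0.0535, lowest 0.0118). Of 16 glucose uptake and glycolysis genes 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.178). Without Ad-Dyrk1b replicate 1 the list passed as higher (camera adjusted p = 0.0479, highest 0.502 with 1 library left out). Pgam1 and Pgk1 rose by 0.39 ± 0.11 each. The call for Pgam1 was kept only without Ad-Dyrk1b replicate 1 (edgeR adjusted p = 0.0350 to 0.112), and that for Pgk1 was lost without any 1 library (edgeR adjusted p = 0.0563 to 0.166). Both were also lost with limma-trend on FPKM. Among annotation terms, Glycolysis / Gluconeogenesis held 12 higher genes of 57 (Fisher's exact test, adjusted p = 0.0265), Pgam1, Pgk1 and Acss2 among them. It was not enriched with genes that changed by 1 log2 unit or more. Negative regulation of gluconeogenesis held 8 higher genes of 20 where 1.47 were expected (Fisher's exact test, adjusted p = 0.00274), and positive regulation of glucose metabolic process held 8 of 15 where 1.10 were expected (Fisher's exact test, adjusted p = 0.000323). Of the 8 genes in each of these terms, 6 are Mup genes.

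Gys2, the liver glycogen synthase, fell by 0.61 ± 0.13 (edgeR adjusted p = 0.0103) and was the 1 gene called of 12 in the glycogen list (1 adjusted over the list alone; camera adjusted p = 0.279). Among 20 insulin signalling genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.661). Grb10, an adaptor that binds the insulin receptor, rose by 0.99 ± 0.19 (edgeR adjusted p = 0.00527). Mlst8, a subunit of both mTOR complexes, fell by 0.51 ± 0.14, a call kept only without Ad-EGFP replicate 2 (edgeR adjusted p = 0.0293 to 0.121). Of 19 secreted regulators of metabolism 5 rose (5 adjusted over the list alone; camera adjusted p = 0.117). Without Ad-Dyrk1b replicate 1 the list passed as higher (camera adjusted p = 0.0401, highest 0.374 with 1 library left out). Serpinb1a, a protease inhibitor, rose by 2.34 ± 0.15 and the peptidase gene Dpp4 by 0.81 ± 0.12. Igfbp2, an IGF-binding protein gene named after its values were seen, rose by 1.81 ± 0.36. Its call was lost without Ad-Dyrk1b replicate 1 or Ad-EGFP replicate 1 (edgeR adjusted p = 0.0848 and 0.121, lowest 0.0264) and without the low-count filter.

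Interferon-response genes were higher, with 17 of 31 called (21 adjusted over the list alone) and a median of 0.80. The antiviral genes Oas3, Oasl2, Irf7 and Isg15 rose by 1.56 ± 0.21, 1.09 ± 0.15, 1.08 ± 0.12 and 0.94 ± 0.17. The list passed (camera adjusted p = 1.82e-08, and camera adjusted p = 0.716 with an estimated correlation). The mean log2 level of its members, centred over the 6 libraries, was 0.57, 0.40 and 0.03 in Ad-Dyrk1b replicates 1, 2 and 3. In Ad-EGFP replicates 1, 2 and 3 it was -0.43, -0.23 and -0.34. Of 15 T and NK cell markers 4 rose (6 adjusted over the list alone), with a median of 0.65. Among them Gzmb (granzyme B) rose by 1.14 ± 0.14. The list passed (camera adjusted p = 6.73e-05, and camera adjusted p = 0.716 with an estimated correlation).

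Markers of blood also stood higher in Ad-Dyrk1b livers, most of all in replicate 3, which had the lowest interferon level of its group. Haemoglobin transcripts reached 857, 1093 and 3754 CPM in Ad-Dyrk1b replicates 1, 2 and 3, against 510, 671 and 828 in Ad-EGFP replicates 1, 2 and 3. The 6 erythroid markers had a median of 1.51 (camera adjusted p = 0.0345, and camera adjusted p = 0.716 with an estimated correlation), which was 0.50 without Ad-Dyrk1b replicate 3. The list did not pass without Ad-EGFP replicate 1 or 2 (camera adjusted p = 0.0653 and 0.0688; lowest 0.00180 with 1 library left out). Its members were called 0 times by edgeR, DESeq2 and limma-voom, adjusted over all genes, and 0 times by edgeR adjusted over the list alone or at an unadjusted p under 0.05. Hbb-bs (beta globin) had 1.49 ± 0.67 (edgeR adjusted p = 0.235), which was 0.58 without Ad-Dyrk1b replicate 3.

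Of 12 endothelial markers 1 was called higher, and 0 by edgeR adjusted over the list alone (5 at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma-voom over all genes). Their median was 0.37 (camera adjusted p = 0.00530, and camera adjusted p = 0.716 with an estimated correlation). Without Ad-EGFP replicate 1 it was 0.24 and the list did not pass (camera adjusted p = 0.0532; lowest 0.000743 with 1 library left out). The groups overlapped in the mean centred log2 level of the endothelial list, with -0.0301 in Ad-Dyrk1b replicate 2 and -0.0251 in Ad-EGFP replicate 3. Markers of resident macrophages, monocytes and neutrophils, and B and plasma cells did not pass (camera adjusted p = 0.0530, 0.0922 and 0.630), with medians of 0.30, 0.51 and 0.39. The resident macrophage list passed as higher with the stricter filter (camera adjusted p = 0.0399) and without Ad-Dyrk1b replicate 2, Ad-EGFP replicate 2 or Ad-EGFP replicate 3 (camera adjusted p = 0.0363, 0.0478 and 0.00585, highest 0.354 with 1 library left out). The monocyte and neutrophil list passed as higher without Ad-Dyrk1b replicate 2, Ad-EGFP replicate 1 or Ad-EGFP replicate 3 (camera adjusted p = 0.00202, 0.0494 and 0.0463, highest 0.360 with 1 library left out). The B and plasma cell list passed as higher without Ad-Dyrk1b replicate 2 (camera adjusted p = 0.0326, highest 0.937 with 1 library left out). Stellate cell and cholangiocyte markers did not pass either (camera adjusted p = 0.243 and 0.171), although the cholangiocyte marker Spp1 (osteopontin) rose by 0.85 ± 0.13. The stellate cell list passed as lower without Ad-EGFP replicate 1 (camera adjusted p = 0.0204, highest 0.512 with 1 library left out). Hepatocyte identity genes did not pass (camera adjusted p = 0.310), and the transcription factor gene Foxa3 fell by 0.72 ± 0.14.

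Acute phase genes went both ways, with 3 of 21 higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.885). Orm3 rose by 1.59 ± 0.26 and Crp (C-reactive protein) by 0.67 ± 0.13. Orm2, named after its values were seen, rose by 1.68 ± 0.30. Its call was lost without Ad-Dyrk1b replicate 1 or 2 or Ad-EGFP replicate 1 (edgeR adjusted p = 0.0695, 0.0705 and 0.0971, lowest 0.00169) and without the low-count filter. Saa3 fell, and Steap4 fell by 0.55 ± 0.12. Of 16 chemokine, cytokine and NF-kB genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.462). Without Ad-EGFP replicate 1 the list passed as lower (camera adjusted p = 0.0493, highest 0.960 with 1 library left out). Cxcl1, a neutrophil chemokine gene, fell by 0.78 ± 0.17, a call lost without Ad-Dyrk1b replicate 2 (edgeR adjusted p = 0.0531, lowest 0.00166). Of 15 antigen presentation genes, 0 were called by edgeR over all genes, over the list alone or at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom (camera adjusted p = 0.867).

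Targets of p53 were lower, with 8 of 17 called (10 adjusted over the list alone) and a median of -0.42. Phlda3, the cell cycle inhibitor gene Cdkn1a and Zmat3 had log2 fold changes of -1.03 ± 0.14, -0.75 ± 0.11 and -0.60 ± 0.13. Cdkn1a stood at 77.0 ± 2.87 FPKM in Ad-Dyrk1b and 138 ± 13.8 FPKM in Ad-EGFP livers (SD, n = 3 each; edgeR adjusted p = 0.000931). Of 25 cell cycle genes 4 fell (4 adjusted over the list alone), with a median of -0.33, which was -0.21 without Ad-EGFP replicate 1. The replicative helicase genes Mcm5 and Mcm7 fell, with -0.61 ± 0.11 and -0.49 ± 0.10. Ccnd1 (cyclin D1) fell by 0.56 ± 0.14, a call lost without Ad-Dyrk1b replicate 3, Ad-EGFP replicate 1 or Ad-EGFP replicate 3 (edgeR adjusted p = 0.0690, 0.0629 and 0.0808, lowest 0.0284). Both lists passed (camera adjusted p = 0.000105 for p53 targets and 0.000267 for the cell cycle). With an estimated correlation both had camera adjusted p = 0.716.

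Of 15 unfolded protein response genes 4 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.29. The chaperone genes Hyou1 and Dnajb9 rose by 0.69 ± 0.13 and 0.64 ± 0.13. Sdf2l1, named after its values were seen, rose by 0.72 ± 0.18, a call kept only without Ad-Dyrk1b replicate 3 or Ad-EGFP replicate 3 (edgeR adjusted p = 0.0154 to 0.0741). Herpud1, a gene of protein degradation at the endoplasmic reticulum, fell by 0.71 ± 0.16, a call lost without Ad-EGFP replicate 2 or 3 (edgeR adjusted p = 0.0606 and 0.0557, lowest 0.00733). Of 15 NRF2 and glutathione genes 2 rose (5 adjusted over the list alone), with a median of 0.35, and the glutathione transferase gene Gsta2 rose by 0.77 ± 0.14. Of 42 cytosolic ribosomal protein genes 3 rose (6 adjusted over the list alone), with a median of 0.30. These 3 lists passed (camera adjusted p = 0.00253, 0.00501 and 1.06e-06), and with an estimated correlation each had camera adjusted p = 0.716. The groups overlapped in the mean centred log2 level of the NRF2 and ribosomal lists. The NRF2 level was -0.170 in Ad-Dyrk1b replicate 3 and -0.0607 in Ad-EGFP replicate 2. The ribosomal level was -0.00960 in Ad-Dyrk1b replicate 2 and 0.0477 in Ad-EGFP replicate 3. Of 16 genes of the ATF4 stress response, 2 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.109). The list passed as higher without Ad-Dyrk1b replicate 3 or Ad-EGFP replicate 2 (camera adjusted p = 0.0320 and 0.0355, highest 0.295 with 1 library left out). The lipoprotein receptor gene Vldlr rose by 1.49 ± 0.19, and Chac1, an enzyme of glutathione breakdown, fell by 1.77 ± 0.28.

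Clock genes moved in both directions, with 1 of 17 higher and 5 lower (2 and 8 adjusted over the list alone; camera adjusted p = 0.0652). The list passed as lower with the stricter filter (camera adjusted p = 0.0122), which leaves out Npas2, and without Ad-Dyrk1b replicate 3 or Ad-EGFP replicate 2 (camera adjusted p = 0.0320 and 0.0484, highest 0.145 with 1 library left out). With an estimated correlation it had camera adjusted p = 0.716. Npas2, a paralog of Clock, rose by 2.93 ± 0.49, at 0.297 ± 0.076 FPKM against 0.040 ± 0.010 FPKM (SD, n = 3 each), which rests on 2 to 4 counts in each Ad-EGFP library. Ciart and Nr1d2, repressors in the clock, fell, with -0.84 ± 0.18 and -0.62 ± 0.12. Bhlhe40 and Per1, named after their values were seen, fell, with -0.48 ± 0.12 and -0.42 ± 0.12. Their calls were lost without Ad-Dyrk1b replicate 2 or Ad-EGFP replicate 1, that for Bhlhe40 also without Ad-Dyrk1b replicate 3 or Ad-EGFP replicate 3, and that for Per1 also without Ad-Dyrk1b replicate 1. With 1 library left out the edgeR adjusted p was 0.0187 to 0.0908 for Bhlhe40 and 0.0457 to 0.166 for Per1. Of 10 DYRK family members and partners 1 fell (1 adjusted over the list alone; camera adjusted p = 0.531). It was Wbp2, a transcriptional coactivator gene, at 42.7 ± 4.10 FPKM against 65.6 ± 3.38 FPKM (SD, n = 3 each), a log2 fold change of -0.54 ± 0.10 (edgeR adjusted p = 0.00522). The paralog Dyrk1a had -0.32 ± 0.14 (edgeR adjusted p = 0.155). Of 5 hedgehog genes tested, Smo (smoothened) fell by 0.97 ± 0.22, a call lost without Ad-Dyrk1b replicate 1 (edgeR adjusted p = 0.0515, lowest 0.0104; camera adjusted p = 0.929 for the list).

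Across the 43 lists tested, 15 passed with the preset correlation and 0 with an estimated one, where 2 had an unadjusted camera p under 0.05. Fry's directional test called 3 lists, the pericentral, female-biased and p53 lists (fry adjusted p = 0.000318, 0.0402 and 0.0427). Fry's mixed test called 29. The authors' deposited table gave 1035 genes as higher and 614 as lower at an adjusted p under 0.05. Of these, 918 and 563 were called in the same direction by edgeR and 0 in the opposite direction, and 19 of the authors' calls were not tested here. The log2 ratio for Dyrk1b in the authors' deposited table was 4.32.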

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

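The groups share replicate numbers, and whether the numbers pair the samples cannot be told. Same-numbered libraries deviated together at r = 0.0245, 0.172 and 0.108, so 2 of 3 exceeded 0.1. Of 6 libraries, 5 correlated best with their own number. With the replicate number as a block, 1109 genes were higher and 774 lower, and the Cyp7a1 log2 fold change was -0.00598. With that block Srebf1 was called lower (edgeR adjusted p = 0.00656), Gls2 was not called (edgeR adjusted p = 0.0579), and the monocyte and neutrophil list passed as higher (camera adjusted p = 0.0172); no other named gene or list changed its call. DESeq2 size factors, the DESeq2 test (1179 higher, 715 lower), limma-voom, no filter and the stricter filter gave counts within 1.5 times of the 972 higher and 635 lower genes. Higher genes numbered 546 with limma-trend on log2(FPKM + 1) and 535 on log2(FPKM + 0.1). These fits applied no TMM normalization. The median log2 fold change of their tested genes was -0.0744 and -0.0891, against -0.00498 in the main fit. Whether this shift is the cause was not tested. With 1 library left out, 612 to 800 genes were higher, 294 to 461 were lower and 855 to 1096 were shared with the authors' calls (918 higher and 563 lower with all 6 libraries), in fits with fewer samples. Dyrk1b stayed at 4.32 to 4.70 in those fits. Lists past the threshold numbered 15 with camera, 0 with an estimated correlation, 3 with fry and 16 to 17 with 1 library left out. Enriched terms fell from 153 (145 higher, 8 lower) to 74 (all higher) with the 430 genes that changed by 1 log2 unit or more, where fewer genes entered. Of 110 named genes besides Dyrk1b, 102 were called, and 0 of these reversed in any setting. Most called genes were named for their values in these same libraries, so this was close to fixed in advance and lends no independent support. Of the uncalled, 4 reversed: Cyp7a1 was at -0.015 with limma-voom, -0.096 on log2(FPKM + 1) and -0.10 on log2(FPKM + 0.1). With 1 library left out Cyp7a1 ranged from -0.12 to 0.31, Pck1 from -0.38 to 0.13, G6pc from -0.39 to 0.12 and Fasn from -0.26 to 0.30; the cause was not tested. At this depth Fabp6, with 0 counts in each Ad-EGFP library, allows a lower bound only, and Sult3a1, Sult3a2, Dct and Npas2 rest on 1 to 6 counts in each Ad-EGFP library.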

Other observations

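Among genes of the urea cycle and amino acid breakdown, 4 of 21 rose and 2 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.432). Oat rose by 1.39 ± 0.16, Prodh (proline dehydrogenase) by 0.88 ± 0.14 and Hal by 0.79 ± 0.15. Gls2 (a glutaminase) fell by 0.53 ± 0.14. Asl (argininosuccinate lyase), named after its values were seen, fell by 0.51 ± 0.15. Both calls were lost without Ad-Dyrk1b replicate 1, Ad-EGFP replicate 1 or Ad-EGFP replicate 3, that for Gls2 also without Ad-Dyrk1b replicate 3 and that for Asl also without Ad-Dyrk1b replicate 2. With 1 library left out the edgeR adjusted p was 0.0120 to 0.120 for Gls2 and 0.0273 to 0.157 for Asl. The call for Gls2 was also lost with limma-trend on FPKM and with the replicate number as a block (edgeR adjusted p = 0.0579 with the block). That for Asl was also lost with limma-voom, with DESeq2 size factors and with the stricter filter. By family, edgeR called 17 of 18 tested Mup genes higher, 8 of 8 Sult2a and Sult3a genes, 6 of 9 Cyp3a genes, 5 of 6 Cyp4a genes, 7 of 13 Cyp2c genes and 2 of 3 Cyp2b genes, and 2 of 4 Saa genes lower. The summed counts of the Cyp4a family rose by 1.39 ± 0.13 and those of the Cyp2b family by 1.10 ± 0.16, while those of the Saa family fell by 1.27 ± 0.21. Those of the Cyp2c family were not called, with 0.27 ± 0.13 (edgeR adjusted p = 0.198). Lists of oxidative phosphorylation, mitochondrially encoded, heat shock and immediate early genes did not pass (camera adjusted p = 0.270, 0.598, 0.462 and 0.630). The oxidative phosphorylation list passed as higher without Ad-EGFP replicate 3 (camera adjusted p = 0.0463, highest 0.807 with 1 library left out).

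Of 3906 annotation terms, 145 were enriched among the higher genes and 8 among the lower (one-sided Fisher's exact test, adjusted). Retinol metabolism held 36 higher genes of 81 where 5.96 were expected (Fisher's exact test, adjusted p = 1.80e-16), and pheromone binding, which the Mup genes carry, 17 of 19. The test counts each gene as independent, so p-values of terms that hold near-identical copies, such as the Mup genes, can be too small. Steroid metabolic process held 35 of 107, bile secretion 24 of 81 and cellular response to interferon-beta 17 of 49. Among lower genes, chromosome held 50 of 453 where 21.8 were expected (Fisher's exact test, adjusted p = 0.000124). DNA replication held 17 of 116, nucleosome 12 of 63 and the p53 signaling pathway 12 of 68. With the 324 higher and 106 lower genes that changed by 1 log2 unit or more, 74 terms were enriched among the higher genes and 0 among the lower, where 62 had an unadjusted p under 0.05. Cellular response to interferon-beta was then not enriched.

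All tests of explanations for the 3 patterns that follow were chosen after the results were seen; the count over other splits of the samples was planned.

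Mup, Cyp and Sult genes were higher in Ad-Dyrk1b livers, in both sex-biased lists. The highest count of 4 Y-linked genes in any library was 3. This argues against animals of different sex in the groups only if Y-linked transcripts were counted. No library exceeded 3 counts, so that cannot be checked here. Reads that only moved between copies would leave family sums in place, but the sums rose by 1.45 ± 0.17 for Mup and 1.05 ± 0.14 for Sult2a and Sult3a. This covers the families as a whole: Mup15, Mup17 and Mup19 held 1.57% of the Mup counts in Ad-Dyrk1b livers and Sult3a1, Sult3a2 and Sult2a7 held 2.03% of theirs, and the Cyp3a sum rose by 0.53 ± 0.13, so reads assigned to another copy cannot be told apart from a change in these genes or in Cyp3a16 and Cyp3a41b. An effect of Dyrk1b on these genes stays a hypothesis, and since no untreated liver was analysed here, a rise in Ad-Dyrk1b cannot be separated from a fall in Ad-EGFP livers.

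Interferon-response genes were higher in Ad-Dyrk1b livers. More blood cannot be told apart from an effect of Dyrk1b, since Ad-Dyrk1b replicates 1 and 2 also had more haemoglobin than each Ad-EGFP library. The margin was small, at 857 CPM in Ad-Dyrk1b replicate 1 and 828 in Ad-EGFP replicate 3, whose mean interferon levels were 0.57 and -0.34. Ad-Dyrk1b replicate 3 had the most haemoglobin and the lowest interferon level of its group. Without it the list's median was 0.92 with 20 genes higher (camera adjusted p = 4.57e-13). The highest camera adjusted p was 5.67e-07 with 1 other library left out, both at the preset correlation. With all 6 libraries camera adjusted p = 0.716 with an estimated correlation. Within the Ad-Dyrk1b group the interferon level thus fell as haemoglobin rose, but every Ad-Dyrk1b library exceeded every Ad-EGFP library in both. T and NK cell markers also had a median of 0.65. More antigen-presenting cells cannot be told apart from a change within cells: Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had a median of -0.17 with a median standard error of 0.247, but resident macrophage markers had a median of 0.30 and monocyte and neutrophil markers 0.51, with 9 of 10 above 0 in each. A weaker overall response to virus in the Ad-EGFP livers cannot be told apart from an effect of Dyrk1b: the higher of the acute phase and chemokine medians was -0.063, but the acute phase members spread widely (SD 0.872). Virus dose per liver was not analysed here and stays open.

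Clock genes moved in both directions. A collection of the livers at a different clock phase was weighed by 5 genes that peak with Arntl, which averaged 0.81, and 10 that peak with Dbp, which averaged -0.50, a difference of 1.31 (0.78 without Npas2, the 1 gene of the 5 that was called). These sets hold the genes in which the pattern was seen, so the difference restates it and decides nothing. Times of collection are not in the labels, so a shift of phase cannot be told apart from an effect of Dyrk1b on clock genes, and both stay open.

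The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1607 genes and 1 of 10 splits gave as many. The highest of the others was 0 by edgeR, with 201 to 638 genes at an unadjusted p under 0.05. Each other split mixes Ad-Dyrk1b and Ad-EGFP libraries on both sides, so the group difference adds to the spread within each side. Few calls there were close to fixed in advance and lend no support.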
